A study of Homo sapiens with 48 samples.

How the data were processed

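The series measured SH-SY5Y cells, a human neuroblastoma line, and SH(15M) cells, which the labels call a chromosome duplication model of Dup15q syndrome. Each line received a control siRNA (siCTL) or an siRNA against UBE3A (siUBE3A), which gives 4 conditions. RNA-seq and whole-genome bisulfite sequencing (WGBS) each had 12 samples, 3 per condition, and ChIP-seq of histone H3 lysine 4 trimethylation (H3K4me3), ChIP-seq of the histone variant H2A.Z and input DNA each had 8 samples, 2 per condition. Samples were placed in groups by the line and siRNA in their labels. Per the labels' protocols, RNA libraries were depleted of ribosomal RNA and made with a directional kit, WGBS libraries with a post-bisulfite kit and ChIP libraries with a ligation kit. BS-Seeker2, TopHat2, edgeR, Bowtie2 and MACS2 were named per the submitters' processing notes, with the genome builds hg38 and hg19 and with no versions or parameters.

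The RNA files held whole-number read counts per RefSeq transcript, as deposited by the authors, with 5 summary lines per library for reads that were not counted. The counting program, its strand setting and the build behind the counts are not given in the sources used here. The H2A.Z lists held broad peaks with a fold enrichment and a −log10 q-value per peak, per the labels and the layout of the deposited files, and the H3K4me3 lists held positions of 1 bp with a score per position, as deposited by the authors. Each such list came from 2 ChIP libraries pooled with an input, per the labels, so the spread between replicates is not in it. The contig names of these lists are those of hg38. The lists of differentially methylated regions (DMRs) and of differential H3K4me3 and H2A.Z regions were the authors' own comparisons on hg19 and held a score per region, as deposited. The DMR score is signed and its sign convention is not given in the sources used here. The score of the differential H3K4me3 and H2A.Z regions is positive throughout and gives no direction. Methylation levels and coverage per site, and the signal of each ChIP library, were not used here, so the depth behind these regions is unknown.

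Transcript accessions were matched to gene symbols in a RefSeq gene table of assembly GRCh38.p14, which matched 49622 of 50694 entries (97.9%). The entries without a match held 3.60 to 5.23% of a library's counted reads and were kept under their accession. The 5 summary lines stayed out of library sizes and tests. Counted reads made up 0.0374 to 0.540% of the reads in a library. Of all entries, 34529 had no read in any library and 3788 passed edgeR's filterByExpr, of which 2686 were protein coding and 487 had a symbol that names an antisense RNA. The tested entries held at least 94.5% of the counted reads of each library. Pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.77 to 4.81. Each library was used as 1 replicate. A difference beyond sampling noise does not show that libraries came from separate cultures.

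Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling and the quasi-likelihood F test on all 12 libraries in 4 groups, which leaves 8 residual degrees of freedom. An entry is called where its Benjamini-Hochberg adjusted p over the 3788 tested entries is under 0.05. The contrasts were siUBE3A against siCTL in each line, SH(15M) against SH-SY5Y with siCTL, SH(15M) with siUBE3A against SH-SY5Y with siCTL, and the difference of the knockdown effects between the lines. Levels are given as CPM, edgeR's TMM-normalised unit of reads scaled to a common library size, as mean ± SD over the 3 libraries of a group. The levels of ACTB, EEF1A1 and GAPDH, the median with the ribosomal protein genes and the range for UBE3A are instead per 1e6 counted reads of a library, without TMM. Where a group had no read, the fold is given against a floor of 3 reads over the summed total of that group. Where it had 1 to 3 reads, the ratio is given with its exact 95% counting interval. Intervals cover counting error only. Floors cover the counting error of the group with 0 reads and not that of the other group. A fold written with at least can therefore exceed the true fold. No source says that replicates came from separate cultures, so p-values measure the spread between these samples.

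The groups, tests, 26 gene lists, 70 alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for each comparison, UBE3A, the 8 largest increases and 8 largest decreases among called entries of at least 1 CPM whose groups did not overlap and whose symbol is not a clone name (5 of each for the difference between lines and for SH(15M) with siUBE3A against SH-SY5Y), up to 4 members of each list with at least 3 calls, all called genes of the 15q11-q13 list and up to 12 called imprinted genes elsewhere. Lists with at least 2 tested entries were tested with limma 3.58.1 by camera with a preset correlation of 0.01, with camera at an estimated correlation and with fry. Of the 26 lists, 20 had enough entries. Genes of chromosome Y and the genes of X inactivation are not reported. Chromosomes were compared by the median log2 fold change of their entries and by camera, with a percentile interval from 10000 bootstrap draws. The alternatives included DESeq2 1.42.0, limma-voom, median-of-ratios scaling, other filters, and leaving out each library in turn. A further 12 alternatives were chosen after seeing the data.

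Region lists were compared with bedtools 2.31.1 and Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A shared region needs an overlap of at least 1 bp. Chance overlap came from 1000 circular shifts within chromosomes. Shares have exact (Clopper-Pearson) 95% intervals. No gene annotation of hg19 was used, so the genes at hg19 regions were not analysed here. Peaks on hg38 were set beside GRCh38 gene spans with a margin of 1 kb.

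The count tests were tested on simulated data drawn from the means and library sizes of the tested entries, with 200 changed entries per run. For the knockdown in SH-SY5Y, 45.0% of entries changed 2-fold and 85.5% of those changed 4-fold were called. The values were 46.0% and 88.5% for the knockdown in SH(15M), and 51.0% and 90.5% for SH(15M) against SH-SY5Y. The share of false calls lay between 2.16 and 10.0% in these 6 runs. With all chromosome 15 entries raised 1.5-fold, camera called chromosome 15 and no other chromosome.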

Results

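Transcript counts, DNA methylation and histone marks were compared in SH-SY5Y neuroblastoma cells and in SH(15M), a derivative that models the chromosome 15 duplication of Dup15q syndrome, each with a control siRNA or an siRNA against UBE3A. UBE3A lies in the imprinted region 15q11-q13 and encodes an E3 ubiquitin ligase. The series held 48 samples: 12 RNA-seq and 12 WGBS libraries, with 3 per condition, and 8 libraries each for H3K4me3, H2A.Z and input, with 2 per condition. The design asks what depletion of UBE3A changes in each line, what the additional chromosome 15 material changes, and whether both act at the same places.

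UBE3A itself had 0 reads in all 12 RNA libraries over its 3 listed transcripts, which allows levels of up to 7.42 to 57.6 reads per 1e6 counted reads, depending on the library. The counts therefore check nothing about the siRNA labels. SNRPN and NDN, paternally expressed genes of 15q11-q13, also had 0 reads in each library. The mRNAs of housekeeping genes were scarce among the counted reads. ACTB reached at most 71.2 reads per 1e6 counted reads in any library, EEF1A1 164 and GAPDH 3.49, without TMM. The highest mean levels, with TMM, were on UGDH-AS1 (15718 CPM) and DBH-AS1 (13887 CPM), which are named as antisense RNAs. DBH, which encodes the enzyme that makes noradrenaline, had 386 reads over the 12 libraries against 36188 for DBH-AS1. Among 635 pairs of a gene and the antisense RNA named after it with at least 50 reads together, the antisense RNA held more reads in 482. The strand setting of the counting is not given in the sources used here, so the values below belong to the listed entry and the level of the gene's own mRNA is uncertain.

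Counted reads per library were 317047 to 404559 in SH-SY5Y with siCTL, 140522 to 270099 in SH-SY5Y with siUBE3A, 323325 to 362673 in SH(15M) with siCTL and 52081 to 286672 in SH(15M) with siUBE3A. The share of reads that aligned to several places was 34.2 to 37.4% and 31.2 to 37.7% in the siCTL libraries of the respective lines, 40.1 to 86.2% in SH-SY5Y with siUBE3A and 34.1 to 93.6% in SH(15M) with siUBE3A. The first principal component of the counts held 56.0% of the variance and separated the siCTL libraries from the siUBE3A libraries in both lines. The second held 14.0%, with SH(15M) siUBE3A replicate 2 at 45.3 and the other 11 libraries between -14.2 and 3.47.

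**Figure D1:**
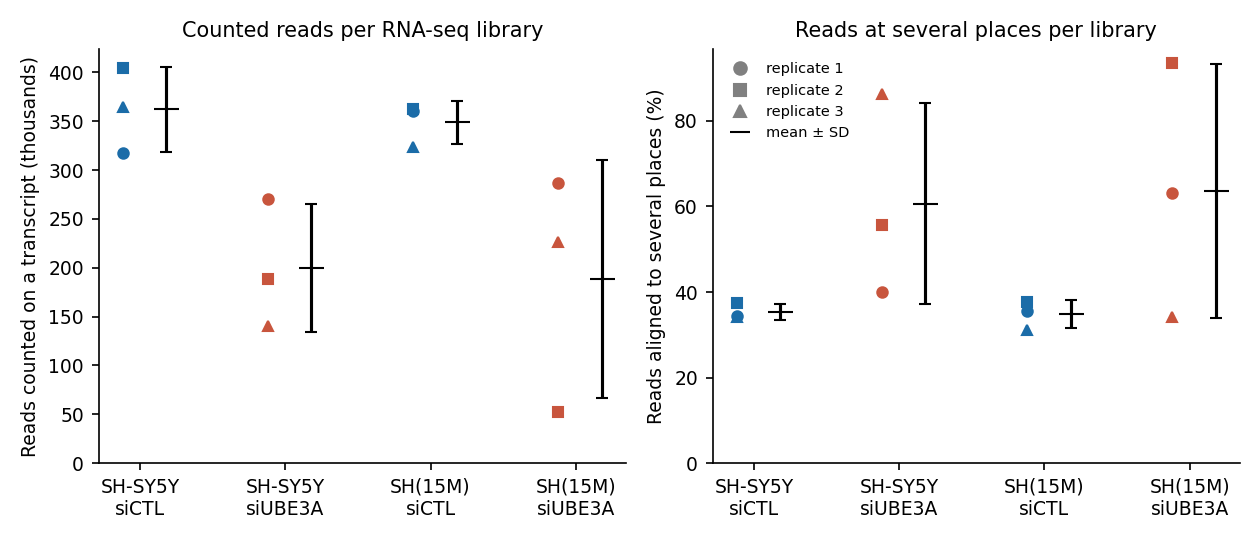
Reads counted on a transcript, in units of 1000, and percent of reads aligned to several places, for each RNA-seq library (points, shaped by replicate, blue for siCTL and red for siUBE3A), with the mean and SD of each group of 3 (bar and whiskers). The siUBE3A groups had means of 199769 and 188478 counted reads, against 362213 and 348995 in the siCTL groups.

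In SH-SY5Y cells, siUBE3A was accompanied by large changes in both directions. PAPPA-AS1, an RNA antisense to the gene of a metalloprotease that cleaves IGF-binding proteins, fell from 2931 ± 341 to 6.49 ± 6.05 CPM (mean ± SD, n = 3 each), with 2968 reads against 3 and a ratio of 0.00183 (counting interval 0.000378 to 0.00536). GNAS-AS1, from the imprinted GNAS cluster on chromosome 20, rose from 2.82 ± 2.91 to 430 ± 150 CPM, a ratio of 158 (counting interval 53.6 to 773). ACTC1, which encodes cardiac actin, had 0 reads in siCTL cells and 103 ± 28.0 CPM with siUBE3A, at least 32.6-fold higher. SLC16A12-AS1 was at least 42.9-fold higher, MIR4655 22.97-fold, TEX47 21.8-fold, C2CD4B 18.7-fold, PCDH9-AS3 16.3-fold and NAV2-AS5 15.7-fold. These were also against 0 reads, with the floor of 3 reads and without the counting error of the siUBE3A reads. In the other direction, entries with 0 reads under siUBE3A included the organic anion transporter family members SLC22A25 (at least 24.5-fold lower) and SLC22A24 (at least 12.1-fold), the polyadenylation factor CSTF2T (at least 21.7-fold), the ribosome assembly factor KRR1 (at least 20.04-fold), ARHGAP22 (at least 18.0-fold), SCGB3A2 (at least 17.1-fold) and ISLR (at least 14.0-fold). Each of these 16 entries was called by edgeR.

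Imprinted genes outside 15q11-q13 moved in both directions in SH-SY5Y, where 1504 of all 3788 entries were called, 737 higher and 767 lower. Of 18 tested entries, 6 rose, 3 fell and 9 did not pass the test, with 12 passing when adjusted over the list alone. IGF2, a fetal growth factor, rose by 5.33 ± 0.61 and 3.15 ± 0.67 on the log2 scale (± SE) on its 2 called transcripts (edgeR adjusted p = 5.18e-11 and 0.000104). The first of these had 3 reads with siCTL and a ratio of 45.3 (counting interval 14.9 to 225). DLK1, a Notch ligand homologue, rose from 87.4 ± 38.2 to 1343 ± 813 CPM, BLCAP rose by 2.82 ± 0.27 and GNAS by 1.23 ± 0.26. The long noncoding RNA KCNQ1OT1 fell by 0.80 ± 0.16, COPG2 fell by 2.41 ± 0.57 and NAP1L5 fell by 3.59 ± 1.03, the last with 1 read under siUBE3A against 27 and a ratio of 0.0672 (counting interval 0.00164 to 0.407). Only HERC2 and MTMR10 could be tested in the list of 34 genes at 15q11-q13 and its neighbourhood. HERC2, which encodes an E3 ubiquitin ligase that binds the UBE3A protein, fell by 1.41 ± 0.33 (edgeR adjusted p = 0.000370), and MTMR10 fell by 1.36 ± 0.43 (adjusted p = 0.00904). Both passed when adjusted over the list alone, but the call of MTMR10 was lost in 3 of 6 fits with 1 library left out (-2.03 to -1.13).

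Of 25 tested entries for cytosolic ribosomal proteins, 11 rose with siUBE3A, 1 fell and 13 did not pass the test, with 15 passing when adjusted over the list alone. RPL24 rose by 1.44 ± 0.23 on the log2 scale, RPL12 by 1.33 ± 0.30 and RPL37 by 2.93 ± 0.70, while RPL31 fell by 2.12 ± 0.61. Ribosomal protein genes have many near-identical pseudogenes, so their counts are uncertain. The siUBE3A libraries in which they were higher were also those with more reads at several places. Among markers of noradrenergic neuroblasts, 4 of 12 rose and 8 did not pass the test (4 when adjusted over the list alone): the transcription factors ISL1 (1.60 ± 0.22), INSM2 (1.82 ± 0.37) and HAND2 (0.57 ± 0.22), and SLC18A2, the vesicular monoamine transporter (0.86 ± 0.25). The neurofilament genes NEFH (0.82 ± 0.21, but -0.00590 and not called with thinned libraries), NEFM (0.70 ± 0.19) and NEFL (0.97 ± 0.38) rose, and the other 3 of 6 neuronal entries did not pass the test, TUBB3 among them at -0.35 ± 0.46. These 3 also passed when adjusted over the list alone. Of 7 Polycomb entries, 3 fell, with 3 when adjusted over the list alone: PCGF3 (-1.21 ± 0.16), EZH1 (-2.21 ± 0.60) and CBX2 (-2.08 ± 0.57). KDM2B was at 0.69 ± 0.40 and did not pass the test. Over all entries 1504 of 3788 were called, so called members are common in any list, and no list passed camera. With 1 library left out, the call of HAND2 was lost in 4 of 6 fits (0.39 to 0.87) and that of NEFL in 3 (0.52 to 1.24).

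The other lists held few tested entries, and the members named here were chosen after their values were seen. In SH-SY5Y, IFIT5 (4.38 ± 0.36) rose and IRF1 (-1.26 ± 0.50) fell among 5 interferon response entries. HK2 (1.26 ± 0.19) and ANKRD37 (0.64 ± 0.23) rose among 5 entries for hypoxia and glycolysis. TYMS (-1.37 ± 0.37) and CCNB2 (-1.99 ± 0.69) fell among 7 entries for the cell cycle. PSMA7 rose (1.25 ± 0.38) and PSMB7 fell (-0.90 ± 0.31) among 6 proteasome entries, and WAC rose (0.99 ± 0.24) and KDM6B fell (-1.60 ± 0.52) among 6 autism risk genes. In each of these 5 lists 2 entries passed when adjusted over the list alone. KMT2D fell among 4 entries for H3K4 methylation, and GFAP, TWIST1, PHGDH and H1-5 each rose as the 1 called member of the lists for glia, mesenchymal cells, the unfolded protein response and histones, with 3, 3, 5 and 3 tested entries. Adjusted over the list alone, 1 entry passed in each of these lists, except for histones with 2. The 5 entries of oxidative phosphorylation, 4 of Wnt targets, 3 of p53 targets and 2 of cholesterol synthesis had no call, over all entries or adjusted over the list alone. Of lists with 1 tested entry, HSPD1 of heat shock rose, GABRQ of the GABA receptors fell, and the entries for H2A.Z exchange and for immediate early genes were not called. DNA methylation enzymes and mitochondrially encoded genes had no tested entry.

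As a whole, 1504 of 3788 entries were called in SH-SY5Y, 737 higher and 767 lower, 1031 of them by at least 2-fold, and 253 had antisense names. DESeq2 called 1266 and limma-voom 1456. The groups did not overlap in 1849 entries (48.8%), where chance gives 10% for 3 against 3. No list passed camera over the 20 lists tested (smallest adjusted p = 0.0806, for ribosomal proteins, and 0.693 with an estimated correlation), while fry, which does not compare a list with other genes, called 9. The camera count was 1 without siCTL replicate 1, 2 without siUBE3A replicate 1 and 1 without siUBE3A replicate 3. The medians of the lists for interferon response, glia, the unfolded protein response and Wnt targets were below 0 where camera's direction was up. Without the 4 libraries in which over 50% of reads aligned to several places, an alternative added after seeing the data, 978 entries were called, and 89 were with all libraries thinned to 52081 counts.

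In SH(15M) cells the same contrast again had PAPPA-AS1 as its largest decrease, from 1490 ± 88.7 to 1.22 ± 2.11 CPM (n = 3 each), with 1474 reads against 1 and a ratio of 0.00126 (counting interval 3.18e-05 to 0.00701). GNAS-AS1 rose from 2.06 ± 1.80 to 247 ± 91.3 CPM, a ratio of 135 (counting interval 36.8 to 1127). SLC16A12-AS1 (at least 40.7-fold), C2CD4B (at least 18.5-fold), INS-IGF2 (at least 16.05-fold) and MIR4655 (at least 9.26-fold) were higher against 0 reads with siCTL. IFIT5, an interferon-inducible RNA-binding protein, rose by 5.46 ± 0.47 on the log2 scale, from 4 to 106 reads, GRM8-AS1 rose by 4.51 ± 0.57, and TEX47 had 30 reads against 1, a ratio of 55.5 (counting interval 9.23 to 2266). A run of neighbouring skeletal muscle myosin genes on chromosome 17 had 0 reads with siUBE3A. MYH4 was at least 13.3-fold lower, MYH8 at least 10.8-fold and MYH13 at least 9.36-fold. Neighbouring entries can share transcripts of a locus, so these may not be separate changes. SCGB3A2 and LDLRAD4-AS1 were each at least 10.4-fold lower, LEF1-AS1 at least 9.90-fold and FZD4, a Wnt receptor, at least 9.54-fold.

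Imprinted genes in SH(15M) followed with 6 entries higher, 4 lower and 8 not called of 18, and 12 passing when adjusted over the list alone. BLCAP rose by 2.76 ± 0.26, the 2 IGF2 transcripts by 4.07 ± 0.70 and 3.02 ± 0.86 with 3 siCTL reads each (ratios 19.1, interval 5.97 to 97.8, and 9.26, interval 2.62 to 49.9), RTL1 by 1.59 ± 0.60 and GNAS by 0.71 ± 0.29. KCNQ1OT1 fell by 0.78 ± 0.16, COPG2 fell by 3.14 ± 0.71 (3 reads against 51, ratio 0.109, interval 0.0217 to 0.337), NAP1L5 fell by 2.68 ± 0.81 (3 against 38, ratio 0.146, interval 0.0289 to 0.461) and CD81 fell by 1.72 ± 0.54. At 15q11-q13, MTMR10 fell by 1.31 ± 0.48 (edgeR adjusted p = 0.0285), and both tested entries passed when adjusted over the list alone. Of 7 Polycomb entries 3 fell, also adjusted over the list alone: PCGF3 (-0.97 ± 0.16), CBX2 (-3.31 ± 0.78, 2 reads against 40, ratio 0.0926, interval 0.0108 to 0.357) and EZH1 (-1.71 ± 0.67), with PHC2 at 0.72 ± 0.34 and not called. ISL1 (1.04 ± 0.22), SLC18A2 (0.88 ± 0.25) and HAND1 (1.39 ± 0.56) rose among 12 noradrenergic entries, 2 when adjusted over the list alone, and INSM2 at 0.78 ± 0.36 did not pass the test. INSM2 was at 0.0220 without siUBE3A replicate 1, and at 1.16 and called without replicate 3. Over all 3788 entries 1230 were called in SH(15M), and no list passed camera. The calls of GNAS, RTL1 and HAND1 were lost in 6, 5 and 5 of 6 fits with 1 library left out. Those of MTMR10 (-1.70 to -0.81), EZH1 (-3.17 to -1.15), SLC18A2 (0.65 to 1.22) and RPL31 (-2.82 to -1.29) were lost in 3. Of 25 ribosomal protein entries, 4 rose, 1 fell and 20 were not called, with 5 passing when adjusted over the list alone. Among these were RPL24 (1.35 ± 0.24), RPL12 (1.33 ± 0.29) and RPS23 (0.67 ± 0.22, chosen after its value was seen) on the higher side and RPL31 (-1.90 ± 0.60) on the lower.

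Of the other lists, whose members were again named after their values were seen, interferon response had IFIT5 higher and IRF1 lower (-1.60 ± 0.52) of 5 entries, hypoxia and glycolysis had HK2 (1.09 ± 0.19) and ANKRD37 (1.40 ± 0.24) higher of 5, neuronal genes had NEFH (1.02 ± 0.21) and NEFM (0.69 ± 0.20) higher of 6, and the proteasome had PSMC1 higher (0.91 ± 0.21) and PSMB7 lower (-1.59 ± 0.36) of 6, with 2 of each list passing when adjusted over the list alone. GINS2 and CCNB2 fell among 7 cell cycle entries (1 over the list alone), and WAC rose and ASH1L fell among 6 autism risk genes (3 over the list alone). KMT2D of H3K4 methylation and TRIAP1 of the p53 targets fell, and TWIST1 of mesenchymal cells, NDUFS7 of oxidative phosphorylation, H2BC12 of the histones and HSPD1 of heat shock rose, each as the 1 call of its list and 1 over the list alone. Glia, the unfolded protein response, cholesterol synthesis, Wnt targets, GABA receptors and H2A.Z exchange had no call by either count, and the immediate early list had none over all entries and 1 over the list alone.

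In SH(15M), 1230 entries were called, 607 higher and 623 lower, with 1014 by DESeq2 and 1185 by limma-voom. The groups did not overlap in 44.0% of entries, against 10% by chance. No list passed camera (smallest adjusted p = 0.401, and 0.713 with an estimated correlation), and fry called 4. The median and camera direction differed in sign for interferon response, cholesterol synthesis and the unfolded protein response. Without the libraries whose reads mostly aligned to several places, 744 entries were called, and 58 were with thinned libraries.

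The knockdown effects in the lines resembled each other entry by entry. PAPPA-AS1, GNAS-AS1, SLC16A12-AS1, C2CD4B, MIR4655, TEX47 and SCGB3A2 were among the largest changes in both, and these contrasts share no library. Across the 3788 entries the log2 fold changes had a Pearson correlation of 0.866 and a Spearman correlation of 0.832, with a slope of 0.788 of SH(15M) on SH-SY5Y. Entries are not independent replicates. Of the called entries, 970 were called in both lines, each in the same direction: 484 higher in both, where independent lists give 118, and 486 lower in both, where they give 126. Among the 1764 called in either line, 97.6% had the same sign. A test of the difference between the lines called 0 entries by edgeR, with 188 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom (smallest edgeR adjusted p = 0.529). None of the 20 lists passed camera for that difference, and the p53 targets, with 0 of 3 entries called, and the ribosomal proteins, with 0 of 25, shared the smallest adjusted p of 0.449 (0.714 with an estimated correlation). No member of any list was called for it, over all entries or adjusted over the list alone, and Wnt targets and the cell cycle had a median below 0 where the direction was up. The correlation was 0.445 over all entries of at least 1 CPM, 0.661 without the libraries with most reads at several places and 0.632 with thinned libraries. In the second of these settings, where each siUBE3A group keeps 1 library that is assumed to vary like the others, 3 entries differed between the lines.

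**Figure D2:**
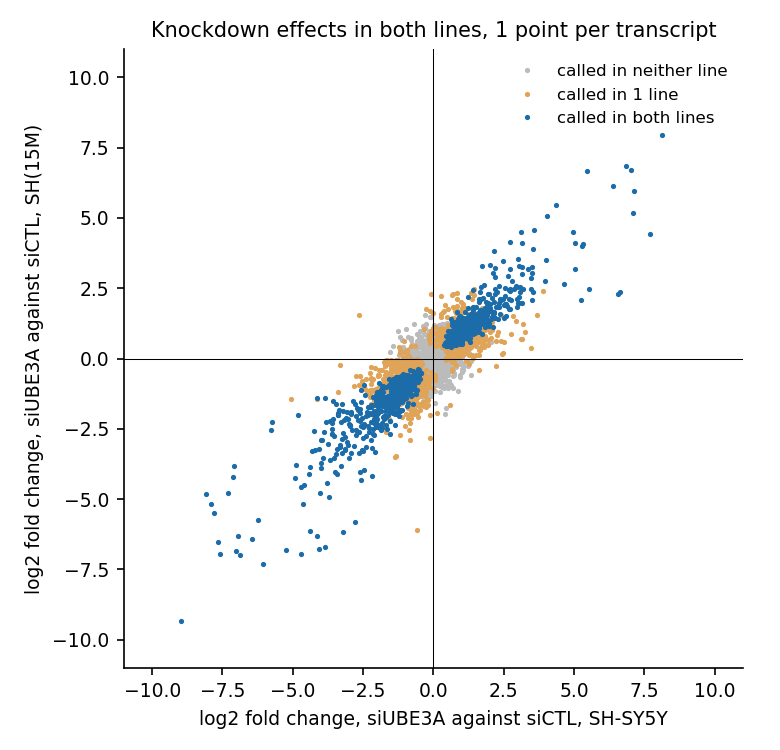
Log2 fold change of siUBE3A against siCTL in SH-SY5Y (horizontal axis) and SH(15M) (vertical axis), with 1 point per tested transcript entry (grey, called in neither line; orange, called in 1 line; blue, called in both). The 970 entries called in both lines lie in the quadrants of equal sign; 2 entries whose levels are not reported here are not drawn.

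Between the lines with siCTL, few entries differed. R3HDM2 was higher in SH(15M), at 447 ± 33.4 against 212 ± 52.4 CPM (n = 3 each; edgeR adjusted p = 0.00121), and was the only call in that direction. SFRP5, a secreted Wnt antagonist, fell by 2.40 ± 0.56 on the log2 scale, KRR1 fell by 2.32 ± 0.42, and the folate receptor genes FOLR1 and FOLR3 on chromosome 11 fell (-1.54 ± 0.33 and -1.19 ± 0.19). CADM3-AS1 fell from 95.3 ± 3.99 to 33.3 ± 7.29 CPM and the proprotein convertase PCSK7 from 270 ± 12.3 to 134 ± 6.28 CPM, and PAPPA-AS1 (-0.98 ± 0.15) and SNAI3 (-0.91 ± 0.20) fell as well. INPPL1, close to FOLR1 and FOLR3 in the annotation and named after its value was seen, fell by 0.75 ± 0.15. In all, 10 entries were called by edgeR, 7 by DESeq2 and 9 by limma-voom. The count was 5 without SH-SY5Y siCTL replicate 3, SH(15M) siCTL replicate 1 or SH(15M) siCTL replicate 2, 6 without SH(15M) siCTL replicate 3, 17 in a fit of the compared groups alone and 0 with thinned libraries. The call of PCSK7 was lost in 6 of 6 such fits, those of SFRP5 and SNAI3 in 5 and that of FOLR1 in 3. None of the 26 lists had a called member, over all entries or adjusted over the list alone, and none passed camera (smallest adjusted p = 0.415, shared by Polycomb and glia, and 0.734 with an estimated correlation). Fry called 1, the Polycomb list (lower, adjusted p = 0.0343). The median and camera direction differed in sign for interferon response, cholesterol synthesis and autism risk genes.

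Entries on chromosome 15 were not higher in SH(15M). Their median log2 fold change was -0.04 (bootstrap interval -0.11 to 0.04), rank 21 of 23 chromosomes, whose other medians ran from -0.10 on chromosome 10 to 0.12 on chromosome 13. The sign of the chromosome 15 median depends on the filter and turned positive with a mean of at least 1 CPM. No chromosome passed camera (smallest adjusted p = 0.311). At 20 to 40 Mb of chromosome 15 in the order of assembly GRCh38.p14, a window chosen after the histone mark lists were seen, 10 tested entries had a median of -0.15 (-0.54 to 0.12) and 0 calls. A gene with 3 copies against 2 would lie at 0.58 if its transcript followed copy number. Simulated data with a 1.5-fold rise of chromosome 15 returned a median of 0.53 over the chromosome (camera adjusted p = 4.28e-46), and medians of 0.33 to 0.90 over 20 draws for 10 entries of the window.

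SH(15M) cells with siUBE3A were also set against SH-SY5Y with siCTL, a contrast that shares libraries with both knockdown contrasts, so that entries in common can come from those libraries. PAPPA-AS1 had 1 read against 2968, a ratio of 0.000648 (counting interval 1.64e-05 to 0.00361). SLC16A12-AS1 was at least 42.3-fold higher and ACTC1, TEX47 and C2CD4B each at least 19.2-fold, while KRR1 (at least 18.9-fold), ARHGAP22 (at least 17.0-fold), SCGB3A2 (at least 16.1-fold) and FZD4 (at least 15.1-fold) were lower. RNA28SN5, a ribosomal RNA that rRNA depletion targets and that is present in many copies, was higher at 13157 ± 20530 against 57.5 ± 30.5 CPM (n = 3 each; edgeR adjusted p = 0.0277), with a spread larger than its mean. Of 18 imprinted entries, 5 rose and 5 fell (12 adjusted over the list alone), with BLCAP up by 3.08 ± 0.27 and COPG2 down from 68 to 3 reads (ratio 0.0848, interval 0.0171 to 0.258). HERC2 fell by 0.78 ± 0.31 and MTMR10 fell by 1.58 ± 0.47, and both passed when adjusted over the list alone. Polycomb members PCGF3 (-1.08 ± 0.16), CBX2 (-3.73 ± 0.75, 2 reads against 55, ratio 0.0699, interval 0.00826 to 0.265) and EZH1 (-2.41 ± 0.63) fell, the noradrenergic genes ISL1 (1.57 ± 0.22), INSM2 (1.52 ± 0.38), HAND1 (1.88 ± 0.59) and SLC18A2 (0.77 ± 0.25) rose, and so did the ribosomal protein genes RPL24 (1.32 ± 0.24), RPL12 (1.52 ± 0.29) and RPS23 (0.91 ± 0.22). Without the libraries with most reads at several places SLC18A2 was at -0.0644, and its call was lost in 5 of 6 fits with 1 library left out (0.54 to 1.10). Calls were likewise lost in 5 fits for DLK1 (2.64 ± 0.83) and in 4 for RNA28SN5, HERC2, PSMA7, PSMC1 and 1 transcript of IGF2 (2.16 ± 0.77). The proteasome genes PSMA7 (1.17 ± 0.39) and PSMC1 (0.60 ± 0.21, but -0.0387 and not called with thinned libraries) rose and PSMB7 fell by 1.70 ± 0.36. These lists had 3 of 7, 4 of 12, 4 of 25 with RPL31 as the 1 decrease, and 3 of 6 entries called, and 3, 4, 4 and 3 over the list alone. Elsewhere, HK2, ANKRD37, NEFH, NEFM, IFIT5, WAC, TWIST1, H2BC12 and HSPD1 rose and IRF1, KDM6B and KMT2D fell, named after their values were seen, and p53 targets, the cell cycle, glia, cholesterol synthesis, the unfolded protein response, oxidative phosphorylation and Wnt targets had no call. In all, 1317 entries were called, 646 higher and 671 lower, with 1042 by DESeq2 and 1272 by limma-voom. The count was 814 without the libraries with most reads at several places and 70 with thinned libraries. No list passed camera (smallest adjusted p = 0.388, and 0.893 with an estimated correlation), and fry called 6. The median and camera direction differed in sign for Wnt targets, interferon response and cholesterol synthesis.

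The longest DMR lists were those between the lines, and the read depth behind each list is not given in the sources used here. The authors' deposited lists held 8678 DMRs for the knockdown in SH-SY5Y, 4560 for the knockdown in SH(15M), 15472 for SH(15M) against SH-SY5Y and 13318 for SH(15M) with siUBE3A against SH-SY5Y with siCTL. In the authors' deposited table, the DMR with the largest absolute score in SH-SY5Y knockdown lay on chromosome 3 at 160822445 to 160823260 (hg19; score -377), in SH(15M) knockdown on chromosome 14 at 102247709 to 102248188 (score -208), and between the lines on chromosome 2 at 20870283 to 20871779 (score 1547). Scores were positive in 41.1% of DMRs of the knockdown in SH-SY5Y (exact interval 40.03 to 42.1%, exact binomial p = 2.08e-62), 48.4% in SH(15M) (p = 0.0318), 48.4% between the lines (p = 6.44e-05) and 48.8% in the list with siUBE3A (p = 0.00634). The DMRs of 1 list come from the same libraries and are not independent. Binomial p-values and intervals for DMRs, here and below, therefore do not measure the spread between libraries. The share for SH(15M) did not pass the test in the higher-scoring part of its list (48.2%, exact binomial p = 0.0821) or among DMRs of at least 300 bp (49.9%). In the last 2 lists it was 50.5 and 50.2% in the higher-scoring part (exact binomial p = 0.345 and 0.713) and 46.2 and 46.6% at 300 bp or more (p = 1.2e-08 and 5.21e-06). Chromosome 19 was the densest in each list, with 6.46 to 19.1 DMRs per Mb, and chromosome X the sparsest, with 0.142 to 0.528. At 20 to 33 Mb of chromosome 15, which holds 15q11-q13, the lists had 16, 10, 92 and 74 DMRs. Of these, 3, 1, 54 and 43 had a positive score (exact binomial test against 50%, unadjusted p = 0.0213, 0.0215, 0.117 and 0.201), where the whole list of the knockdown in SH-SY5Y has 41.1%. In the authors' deposited table, the largest there between the lines lay at 22545046 to 22546834 (score 545) and 28049975 to 28051008 (score 235).

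Some regions were listed for the knockdown in both lines. Of the 8678 DMRs in SH-SY5Y, 409 overlapped a DMR of SH(15M), where circular shifts gave a mean of 7.02 and at most 16 (p = 0.000999, the smallest that 1000 shifts can give), and 58.0% of the 410 overlapping pairs had scores of the same sign (exact binomial p = 0.0013). These lists share no library. The shifts move regions to any position of a chromosome, also where no DMR can be listed. Lists unrelated to each other can therefore exceed them too, so this p alone does not show shared sites of the knockdown. Larger overlaps came from lists that share libraries. The knockdown in SH-SY5Y and the comparison of the lines share SH-SY5Y siCTL and had 2053 overlaps with 90.8% of equal sign. The knockdown in SH(15M) and the comparison of the lines, in which SH(15M) siCTL takes opposite roles, had 1187 overlaps with 7.23% of equal sign. Part or all of such overlap can come from the shared libraries.

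H2A.Z peaks were fewest in SH-SY5Y with siCTL. The lists held 1817 peaks there (1.11 Mb), 9028 with siUBE3A (7.08 Mb), 11990 in SH(15M) with siCTL (10.1 Mb) and 10602 in SH(15M) with siUBE3A (8.50 Mb). No test of these numbers is possible, because each list pools its libraries. The authors' differential H2A.Z lists held only 58 regions for the knockdown in SH-SY5Y, 38 of them on an unplaced contig, and 351 for SH(15M) against SH-SY5Y. The numbers of peaks alone therefore do not show a change in H2A.Z. Of the peaks in SH-SY5Y siCTL, 82.8% overlapped a peak with siUBE3A and 86.1% a peak of SH(15M) siCTL, and 62.0% of SH(15M) siCTL peaks overlapped one with siUBE3A. The largest fold enrichments in the authors' deposited lists were 5.01 at EIF3C (chromosome 16, 28688531 to 28688875, hg38) in SH-SY5Y siCTL, 8.74 at SERHL2 (chromosome 22, 42565094 to 42565399) with siUBE3A, 4.65 at FAM66B (chromosome 8, 7354761 to 7355321) in SH(15M) siCTL and 4.97 at SLX9 (chromosome 21, 44939494 to 44940317) in SH(15M) with siUBE3A. Of H2A.Z peaks, 64.3 to 72.5% held an H3K4me3 position of the same condition. H3K4me3 lists had 26143 and 25074 positions in SH-SY5Y with siCTL and siUBE3A, and 29914 and 37678 in SH(15M). Of those in SH-SY5Y siCTL, 71.8% had a position with siUBE3A within 500 bp.

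Chromosome 15 was over-represented among the mark differences between the lines. Of 1403 differential H3K4me3 regions for SH(15M) against SH-SY5Y, 190 lay on chromosome 15, a share of 13.5% (exact interval 11.8 to 15.4%) against 3.198% of SH-SY5Y siCTL positions (Fisher's exact test, odds ratio 4.74, p = 1.5e-56, Benjamini-Hochberg adjusted p = 1.2e-55 over 8 lists). Of 351 differential H2A.Z regions, 91 did, a share of 25.9% (21.4 to 30.8%) against 3.76% of SH(15M) siCTL peaks (Fisher's exact test, p = 6.86e-46). With siUBE3A in SH(15M), the shares were 10.3% of 2555 H3K4me3 regions (Fisher's exact test, p = 7.85e-52) and 44.0% of 109 H2A.Z regions (p = 8.54e-38). Within chromosome 15, 168 of 190 H3K4me3 regions (88.4%) and 86 of 91 H2A.Z regions (94.5%) of the comparison of the lines lay at 20 to 40 Mb. The regions with the largest H3K4me3 scores in the authors' deposited table were on chromosome 15 at 29966664 to 29968046 (score 58.8), in the overlapping region 29966809 to 29968071 (score 51.8) and at 35087378 to 35088154 (score 33), and the largest H2A.Z score was at 34880646 to 34881015 (score 13.1). Neighbouring regions are not independent, and with overlapping regions merged the H3K4me3 share was 10.6%.

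**Figure D3:**
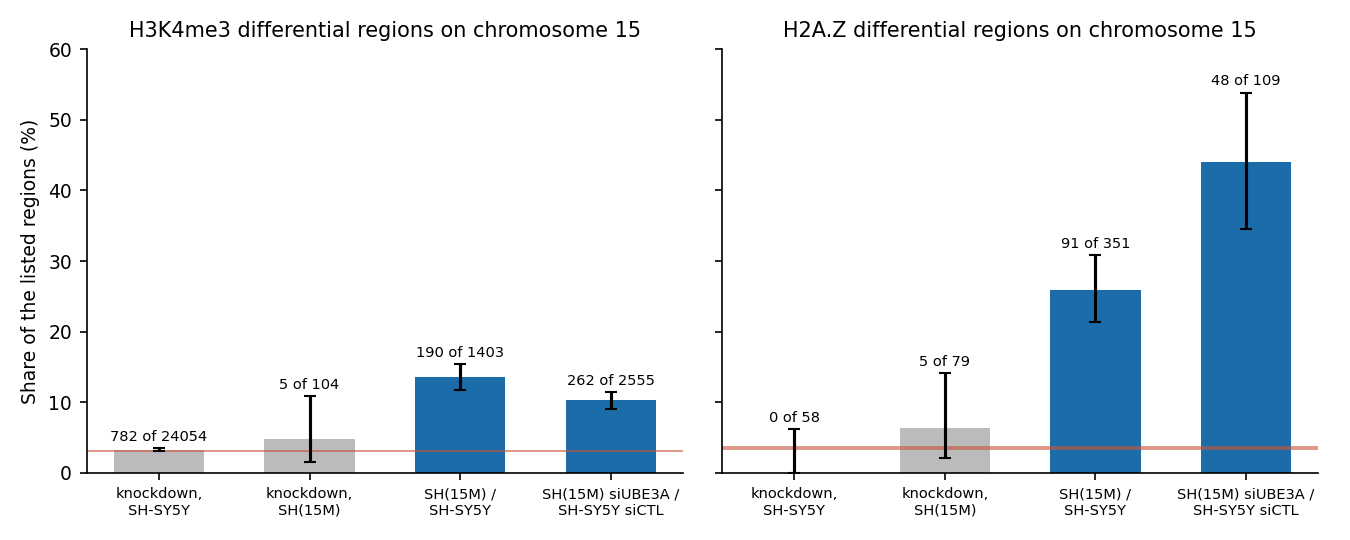
Percent of the deposited differential regions that lie on chromosome 15, for H3K4me3 and H2A.Z in 4 comparisons (bars, with exact 95% intervals as whiskers and counts above; grey for knockdowns, blue for comparisons of the lines), and the range of chromosome 15 shares over the 4 peak lists of the mark (red band). The bars for the comparisons of the lines, 10.3 to 44.0%, stand above the bands of 3.003 to 3.198% and 3.25 to 3.76%.

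**Figure D4:**
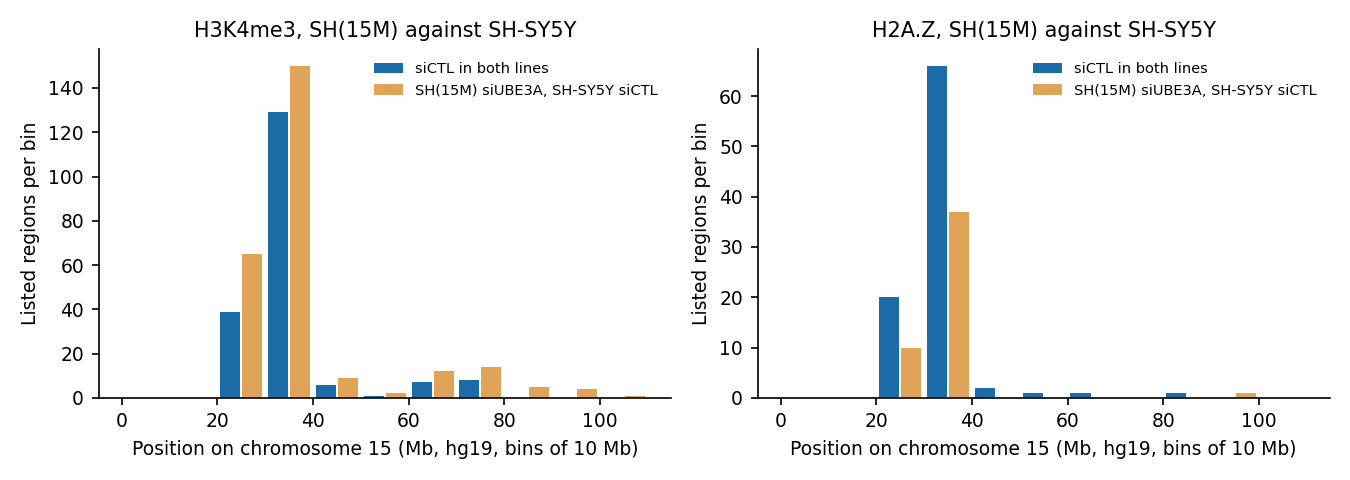
Number of deposited differential regions per 10 Mb bin of chromosome 15 (hg19), for H3K4me3 and H2A.Z, with siCTL in both lines (blue) and with siUBE3A in SH(15M) (orange). The bins at 20 to 40 Mb hold 168 of 190 and 86 of 91 regions with siCTL in both lines.

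No excess on chromosome 15 was called in the knockdown lists, 3 of which hold few regions. Differential H3K4me3 regions numbered 24054 in SH-SY5Y, with 3.25% on chromosome 15 (3.03 to 3.48%, p = 0.742), and 104 in SH(15M), with 4.81% (1.58 to 10.9%, p = 0.391, Fisher's exact test). The median score per H3K4me3 position was 14.7 in SH-SY5Y siCTL and 95.7 with siUBE3A, and 41.0 and 25.9 in SH(15M). A difference in signal over all positions was not separated from changes at single regions. The numbers 24054 and 104 therefore do not compare the effect of siUBE3A between the lines. The densest 5 Mb of the SH-SY5Y list lay on chromosome 6 at 30 to 35 Mb, with 767 regions, and its largest scores were on chromosome 7 at 1703836 to 1708229 (score 15.8), chromosome 11 at 60691798 to 60693305 and chromosome 3 at 113415859 to 113416618 (scores 14.9). In the authors' deposited table of the knockdown in SH(15M), the largest score was on chromosome 5 at 95194659 to 95194875 (score 7.46), and 45 of the 104 regions overlapped one of SH-SY5Y. The SH-SY5Y list is nearly as long as the list of all H3K4me3 positions in SH-SY5Y siCTL (26143), and chance overlap was not computed. Differential H2A.Z regions numbered 58 in SH-SY5Y and 79 in SH(15M), with 0 overlaps between them. Of the 58, 38 lay on the unplaced contig gl000220 and 0 on chromosome 15, which allows a share of up to 6.16% by the exact interval. Of the 79, 5 lay on chromosome 15 (6.33%, 2.09 to 14.2%, p = 0.226, Fisher's exact test). The interval of the H3K4me3 list of SH(15M) includes the 10.3% of the comparison of the lines with siUBE3A.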

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

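The tests of copy number behind the marks, of the RNA libraries' origin, of transcript levels against copy number, of abundant antisense RNA, of ambiguous reads, of handling, of thinned libraries and of the splits by siCTL libraries kept were chosen after the result, or the data behind it, were seen, and the share of reads at several places was looked at because it stood outside the counts used.

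In both lines the siUBE3A libraries held more reads aligned to several places than any siCTL library of the same line, with 1 exception. The shares were 40.1, 55.6 and 86.2% in SH-SY5Y siUBE3A replicates 1, 2 and 3, above the highest siCTL value of 37.4%. They were 63.1 and 93.6% in SH(15M) siUBE3A replicates 1 and 2, above 37.7%, while replicate 3 had 34.1%.

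The first pattern is that counted reads lie on antisense RNAs and hardly on abundant mRNAs. Reads left out as ambiguous between transcripts of a gene do not account for it, since ACTB and EEF1A1, with a single listed transcript each, reached at most 164 reads per 1e6 counted reads, and an abundance of antisense RNA alone does not either, since the median of ribosomal protein genes, ACTB, GAPDH and EEF1A1 was at most 31.8 on that scale in any library. The antisense RNA held more reads than its partner in a share of 0.759 of 635 pairs (0.724 to 0.792). In the siCTL libraries, 61.6 to 68.0% of reads lay on no listed entry, against 0.493 to 0.540% counted. The reads on no entry were not split by strand. Both values are what a directional library counted on the opposite strand would give. In that case an entry such as GNAS-AS1 or PAPPA-AS1 may hold reads of the overlapping gene, and UBE3A at 0 reads would say nothing of the knockdown. The pair of PAPPA-AS1 goes the other way, with 5395 reads on PAPPA and 4446 on PAPPA-AS1 over the 12 libraries. Per 1e6 counted reads, PAPPA also fell with siUBE3A, from 2200 to 2905 to 233 to 370 in SH-SY5Y. In SH(15M) it fell from 1897 to 2230 to 300 to 346. No biological explanation was tested beyond the abundance of antisense RNA.

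The second pattern is the size and likeness of the knockdown effects in both lines. Fewer counted reads in the siUBE3A libraries do not by themselves account for the likeness, since the correlation was still 0.632 with all libraries thinned to the smallest total, against 0.866 without thinning. A correlation does not measure the size of the effects, so a part of fewer reads in the size was not tested. Ribosomal or repeated RNA stays open: in the siUBE3A library of each line with the fewest reads at several places, the effect on entries called without it had slopes of 0.719 to 0.806 in SH-SY5Y and 0.684 to 0.762 in SH(15M) over the 3 siCTL libraries held out in turn, and the lowest, 0.684, lies between the bounds of 0.25 and 0.75 set for the test. Cells of a different stock, day or handling behind each siRNA cannot be told apart from the siRNA, since no library crosses them; 81 entries were at 0 in all 6 libraries of 1 siRNA and counted in all 6 of the other, 76 of them with reads only under siCTL. The siUBE3A libraries hold fewer counted reads, down to 52081 with 5168 entries detected, so entries seen in all 6 of them are fewer at the outset, and the 76 gives no direction by itself. Loss of UBE3A, which the design names, may also be the source and was not tested apart from these.

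The third pattern is chromosome 15, which stood out in the mark lists between the lines and not in the RNA. More copies behind the marks cannot be told apart from other differences between the lines. The share passed Fisher's exact test in all 4 lists between the lines and in 0 of 4 knockdown lists, 3 of them with few regions, but this is the pattern itself. The 2 lists of each mark share the SH-SY5Y siCTL libraries, and their scores give no direction, so a gain is not shown. The regions at 20 to 40 Mb may mark the additional segment. For the RNA, libraries from cells without the additional chromosome and transcript levels that do not follow copy number cannot be told apart. The median was -0.0446 over chromosome 15 and, in the window added after the marks were seen, -0.15 with siCTL and -0.04 (-0.49 to 0.32) with siUBE3A in both lines, with 0 calls over 10 entries, and both explanations give such values. If the counts lie on the opposite strand, these entries may hold reads of overlapping transcripts. What they then report about copy number was not tested.

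Splits of the 6 libraries of each comparison are 10 in number, too few for a share under 0.05. The real counts of 1504, 1230, 10 and 1317 called entries (knockdown in SH-SY5Y, knockdown in SH(15M), lines, lines with knockdown) stand beside a highest value of 0 in the other splits, so 1 of 10 splits reached each. For lists, the real 0 was reached by 10 of 10 splits in each comparison, with 3, 1, 1 and 2 as the highest other values, and any split reaches a real 0. The absolute chromosome 15 median of 0.0446 was reached by 3 of 10 splits, the highest other being 0.0846.

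For the difference of the knockdown effects between the lines, 100 splits of the siRNA labels within lines were drawn, and 100 of 100 gave as many entries as the real 0 and as many lists as the real 0. Any split reaches a real 0, so these 2 shares say nothing about chance. The highest other values were 756 entries and 3 lists. A split calling 756 entries points to a structure of the samples, which follows the siRNA arms: calls came from 7 of the 10 splits in which the number of siCTL libraries kept as controls differed by 2 between the lines, and from 0 of 41 and 0 of 49 splits in which it differed by 0 and 1. For the correlation of 0.866, 1 of 100 splits, the real one, reached it, with 0.630 as the highest other. The other splits mix the siRNA arms in at least 1 line. The result therefore shows that the arms differ alike in both lines, and it does not separate the siRNA from other differences between the arms.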

How the results depend on the processing

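Among the alternatives chosen only after the data were seen were those without the libraries whose reads mostly aligned to several places and with thinned libraries. Those without small and structural RNAs, with merged regions and with sharing within 500 bp were also chosen then. Of the 127 results on named genes, 1680 of 1921 comparisons with an alternative kept direction and side of the threshold, 235 kept the direction and no longer passed, 1 passed anew and 5 reversed. Of the results that answer a comparison, 121 of 179 alternatives other than leaving out a library stayed as they were, 57 moved and 1 reversed. Median-of-ratios scaling, DESeq2, limma-voom, counts summed per gene symbol, and leaving out small and structural RNAs kept each count of called entries within 1.5 times.

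With a library left out in turn, called entries were 1222 to 1421 (knockdown in SH-SY5Y), 870 to 1126 (knockdown in SH(15M)), 5 to 9 (lines), 945 to 1220 (lines with knockdown) and 0 (difference of the knockdowns). The entries that remained called were 1142 to 1311, 821 to 1064, 5 to 8 and 883 to 1139, and none changed sign. Lists passing camera for the knockdown in SH-SY5Y were 0 to 2 and otherwise 0, the chromosome 15 median was -0.05 to -0.00204, and the correlation of the knockdown effects was 0.804 to 0.849. Without SH-SY5Y siCTL replicate 3, TUBB3 was at 0.117 in SH-SY5Y, and without siCTL replicate 2 at -0.610.

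With a mean of at least 1 CPM as the filter, the correlation was 0.445 and the chromosome 15 median 0.0436. Entries called in at least 1 line gave a correlation of 0.901. A fit of the compared groups alone called 17 between the lines. Fry called 9, 4, 1 and 6 lists where camera called 0, since it does not compare a list with other genes. Without the libraries whose reads mostly aligned to several places, the counts were 978, 744, 18, 814 and, for the difference of the knockdowns, 3, with 1 list for the knockdown in SH-SY5Y and a correlation of 0.661. Each siUBE3A group then keeps 1 library, assumed to vary like the other groups. INSM2 was then at -0.0903 (knockdown in SH(15M)) and SLC18A2 at -0.0644 (lines with knockdown). With libraries thinned to 52081 counts, 89, 58, 0 and 70 entries were called, the correlation was 0.632, NEFH was at -0.00590 (knockdown in SH-SY5Y) and PSMC1 at -0.0387 (lines with knockdown); depth limits these counts. Other causes were not tested.

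Whether the replicate numbers pair the samples is not settled. Correlations of same-numbered libraries were low (-0.0435 to 0.132), with 2 of 18 above 0.1. In 10 of these 18 pairs, however, the same number gave the best correlation. With the replicate block, 1497, 1237, 10, 1306 and 0 entries were called and 0 lists, the chromosome 15 median was -0.03 and the correlation 0.868.

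The 50% of each region list with the higher scores holds, by construction, fewer regions: 4339, 2280, 7736 and 6659 DMRs, with positive shares of 50.5% (lines) and 50.2% (lines with knockdown), 12027, 52, 701 and 1277 differential H3K4me3 regions, 29, 39, 175 and 54 differential H2A.Z regions, 13071, 12537, 14957 and 18839 H3K4me3 positions, and 908, 4514, 5995 and 5301 H2A.Z peaks. DMRs of at least 300 bp numbered 1790, 843, 5591 and 4455. With at least 50% of both DMRs shared, overlaps were 136 between the knockdowns, 816 and 762 of SH-SY5Y knockdown with the lists between the lines, 548 and 629 of SH(15M) knockdown with them, and 3368 between those lists. With the same direction only, 237 were left between the knockdowns and 86 of SH(15M) knockdown with the lines. Merged, the H2A.Z regions of SH-SY5Y knockdown were 34. H3K4me3 positions within 500 bp were 18782 (SH-SY5Y siCTL with siUBE3A), 21305 (siCTL of both lines) and 26367 (SH(15M) siCTL with siUBE3A). H2A.Z peaks sharing at least 50% of both were 967 (SH-SY5Y siCTL with siUBE3A) and 871 (siCTL of both lines). The planned test of called genes with a differential H3K4me3 region at the transcription start was not run, since no hg19 annotation was used.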

Other observations

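The tests of peaks at gene spans, of neighbouring entries and of peaks at 20 to 40 Mb were chosen only after the data were seen.

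H2A.Z peaks at 15q11-q13 differed between the peak lists. Of the 34 genes in the list for that region, 0 had an H2A.Z peak within 1 kb of their span in SH-SY5Y siCTL, 9 in SH-SY5Y siUBE3A, 15 in SH(15M) siCTL and 15 in SH(15M) siUBE3A. UBE3A itself, and CYFIP1, NIPA1, OCA2, APBA2, TJP1 and FAN1, had a peak in each of the last 3 lists. H3K4me3 positions were present at 24 of the 34 genes in each condition. Among 58 imprinted genes elsewhere, 8, 24, 23 and 17 had an H2A.Z peak. IGF2, H19, DLK1 and NAP1L5 had one in SH-SY5Y siUBE3A and in none of the other 3 lists, and PEG10, SGCE and IGF2R had one in all 4. SH-SY5Y siCTL had the shortest list, 1817 peaks, and lists from pooled libraries give no test between conditions. The differential H2A.Z list of the knockdown in SH-SY5Y held 0 regions on chromosome 15.

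On chromosome 15, 95 of 451 H2A.Z peaks of SH(15M) siCTL (21.1%) lay at 20 to 40 Mb (hg38), against 6 of 59 (10.2%) in SH-SY5Y siCTL. With siUBE3A these were 74 of 392 (18.9%) and 34 of 315 (10.8%). For H3K4me3 positions the numbers were 183 of 944 (19.4%) and 128 of 836 (15.3%) with siCTL, and 230 of 1198 (19.2%) and 140 of 753 (18.6%) with siUBE3A. Of DMRs on chromosome 15, 140 of 498 (28.1%) lay there on hg19 between the lines, and 30 of 285 (10.5%) and 16 of 121 (13.2%) for the knockdowns.

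Among genes called higher with siUBE3A in SH-SY5Y, 260 had an H2A.Z peak only in the siUBE3A list and 5 only in the siCTL list. Among genes called lower, 199 and 13 did (Fisher's exact test, odds ratio 3.40, p = 0.0268, 1 of 4 such tests). Fisher's exact test gave p = 0.543 for H3K4me3 in SH-SY5Y, and 0.681 and 0.683 for H3K4me3 and H2A.Z in SH(15M). None of the 4 is below 0.05 after adjustment.

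Entries within 50 kb of each other had correlated values. Over 871 neighbouring pairs the log2 fold changes had a correlation of 0.342 for the knockdown in SH-SY5Y, 0.305 in SH(15M) and 0.167 between the lines, where the highest of 1000 random draws was 0.126, 0.121 and 0.1201. Neighbours that overlap can share transcripts of the same locus, which was not separated here.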
